A study of Mus musculus with 6 samples.

How the data were processed

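Inguinal white adipose tissue of male wild-type mice was profiled by RNA sequencing in 3 samples on a high-fat diet (HFD) and 3 on a high-fat diet with 0.5% hesperidin (HEP), all carrying the same batch label. Per the labels' protocols, total RNA was isolated with TRIzol, and libraries were made with a TruSeq RNA kit from 1 µg of RNA, selected for inserts of 300 bp and amplified over 15 cycles of PCR. The labels did not state whether the kit kept strand or which selection of RNA it used.

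The deposited table held TPM values per gene and sample, made by the authors, with their mean TPM per group. The submitters' processing notes name fastp, HISAT2, RSEM, StringTie and DESeq2, without versions or roles. The genome build and the annotation release are not given in the sources used here. Each TPM column had the same total within rounding (999999.71 to 1000000.7), and the deposited group means equalled the means of the sample columns within 3.3e-05 TPM. TPM divides by transcript length and by the library's total, so a rise of abundant transcripts in a library lowers the values of all its other genes, and reads of overlapping or near-identical genes are shared out by the authors' estimate. TPM keeps no read depth. Depth per sample was therefore unknown, intervals and detection limits that need it were not given, and a value of 0 is reported as listed at 0.

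Genes were named as in the deposited table. Of its gene IDs 51884 (90.7%) were found in GENCODE mouse release M21, and 97.0% of those of tested genes. Since the table also holds IDs newer than that release, no coordinates were printed, and the release was used only to find which genes overlap. A blank name was found for 62 tested genes, which are identified by ID and were not named.

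Samples were grouped by their titles. Genes with a mean of at least 1 TPM over the 6 samples were tested, 15446 of 57180. Values were transformed to log2(TPM + 1), and HEP was compared with HFD in limma 3.58.1 (R 4.3.3) with an intensity trend in the variance prior and Benjamini-Hochberg adjustment over all genes tested, two-sided, with a threshold of 0.05. A log2 fold change is on the log2(TPM + 1) scale, which understates the change of genes with low values. Standard errors and 95% intervals are the moderated ones of limma. For single values per library, such as the mean of a list, exact two-sided permutation tests were used, for which 3 samples against 3 cannot give a p under 0.1.

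The 34 gene lists (adipocyte functions, mitochondrial pathways, stromal, vascular, immune, muscle, nerve, skin and blood cell markers, and signalling) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 34 lists. Camera with a correlation estimated from the data and fry were run beside it. With 3 samples per group and libraries that differ in cell content, members of a list move together, which the preset correlation does not take into account. Gene ontology, KEGG and Reactome terms of the deposited annotation with 15 to 300 tested genes were tested with camera in the same manner. In each list, 0 genes passed over all genes and 0 passed adjusted over the list alone, where the smallest adjusted p of any list was 0.0993 in limma.

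The rule for named genes had 3 parts. The first took the 10 genes with the largest fold change in each direction among those past the threshold whose groups did not overlap, filled up with the smallest unadjusted p, and left out predicted genes and immunoglobulin and T cell receptor segments. The second took up to 4 members with the smallest p of each list past its threshold and up to 2 of other lists. The last was fixed: Ucp1, Lep, Adipoq, Pparg, Fasn, Slc2a4, Adgre1, Ccl2, Tnf and Col1a1. Genes outside this rule are named as chosen after their values were seen.

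The gene and list tests were tested on simulated data built from the real libraries before use. For the comparison of HEP with HFD over 15446 genes, with independent noise per gene, limma recovered 13.7% of genes changed 2-fold, 56.7% of those changed 4-fold and 77.1% of those changed 8-fold. With noise shared between genes as in the real residuals, the shares were 14.3%, 50.2% and 70.7%. With no list effect and shared noise, camera with the preset correlation called a median of 15.5 of the 34 lists and 28 at most in 10 simulated data sets, and 0 with an estimated correlation. With independent noise it called a median of 0 and 1 at most. List effects were not simulated, so the share of true list effects that either setting finds is unknown.

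The alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, no filter beyond a value above 0 in a sample, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, the replicate number as a block, robust empirical Bayes, sample quality weights, leaving out mitochondrially encoded genes, leaving out each replicate in turn, other thresholds, camera with an estimated correlation and fry. Chosen after seeing the data were lymphoid and muscle covariates, nuclear protein-coding genes alone, scaling to the adipocyte identity list, leaving out both libraries highest in liver transcripts, and fits within the 3 libraries low and the 3 libraries rich in lymphocyte genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.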

Results

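Gene expression was measured by RNA sequencing in inguinal white adipose tissue, the subcutaneous fat depot of the groin, of male wild-type mice. The 6 libraries fell into 2 groups of 3 samples, a high-fat diet alone (HFD) and a high-fat diet with 0.5% hesperidin (HEP), and the diets lasted 12 weeks. Hesperidin is a flavonoid glycoside of citrus peel. The series also describes a control diet, gut bacterial sequencing and serum metabolites, which were not analysed here. Abundance was given as TPM, the share of transcripts scaled to a fixed total per library, for 57180 genes, of which 15446 reached a mean of at least 1 TPM and were tested, 13000 of them protein-coding. Between 22599 and 25271 genes per library had a TPM above 0. Read depth was unknown, because TPM keeps no depth, so no counting interval could be given. The labels did not say whether each sample came from a separate animal, so the p-values measure only the spread between these samples.

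The question set by the design was how hesperidin changed gene expression in this fat depot on a high-fat diet. At the level of single genes, no change passed the test. With limma on log2(TPM + 1), 0 genes were higher and 0 genes were lower in HEP at an adjusted p under 0.05, and the smallest adjusted p was 0.78. At an unadjusted p under 0.05 there were 105 higher and 174 lower genes, 279 together, where chance alone gives about 772 of 15446. The 3 HEP values lay entirely above the 3 HFD values for 290 genes and entirely below for 553, together 5.46% of the tested genes, against 10% by chance. The median standard error of a log2 fold change was 0.27, and the median half-width of its 95% interval was 0.65. Without HEP replicate 2, 1 gene passed, the small nuclear RNA gene Gm25541, which was chosen for naming after its values were seen. It was listed at 0 in the 3 HFD libraries and in HEP replicate 2, at 57.6 TPM in HEP replicate 1 and at 90.0 TPM in HEP replicate 3.

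The libraries differed far more by their content of lymphocyte genes than by diet. The B and plasma cell list had a mean log2(TPM + 1) of 1.64 and 1.65 in HFD replicates 1 and 2 and of 1.62 in HEP replicate 2, against 6.04 in HFD replicate 3 and 6.89 and 6.94 in HEP replicates 1 and 3. Cd79b, the B cell receptor signalling chain, had 1.77, 1.89 and 149 TPM in HFD replicates 1 to 3 and 252, 2.95 and 300 TPM in HEP replicates 1 to 3. Pax5, the transcription factor of B cell identity, was high in the same 3 libraries, with 0.55, 0.23 and 28.1 TPM in HFD and 55.0, 0.75 and 62.9 TPM in HEP. The T and NK cell list had means of 0.74, 1.27 and 4.69 in HFD and of 5.13, 1.04 and 5.19 in HEP. The first principal component held 62.3% of the variance and separated the same libraries, with scores of -59.1, -50.5 and 41.3 in HFD and 73.9, -77.2 and 71.5 in HEP. Because this content was high in 1 HFD library and in 2 HEP libraries, it moved in part with the diet groups. Fits with the lymphoid content as a covariate, and fits within the 3 libraries low and the 3 rich in lymphocyte genes, were chosen after seeing the data. Each within-library fit has an arm of 1 library, HEP replicate 2 alone among the low and HFD replicate 3 alone among the rich, which is assumed to vary like the others, and 0 lists passed in either with an estimated correlation. Their p-values compare these libraries and are given as support for no call.

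**Figure D1:**
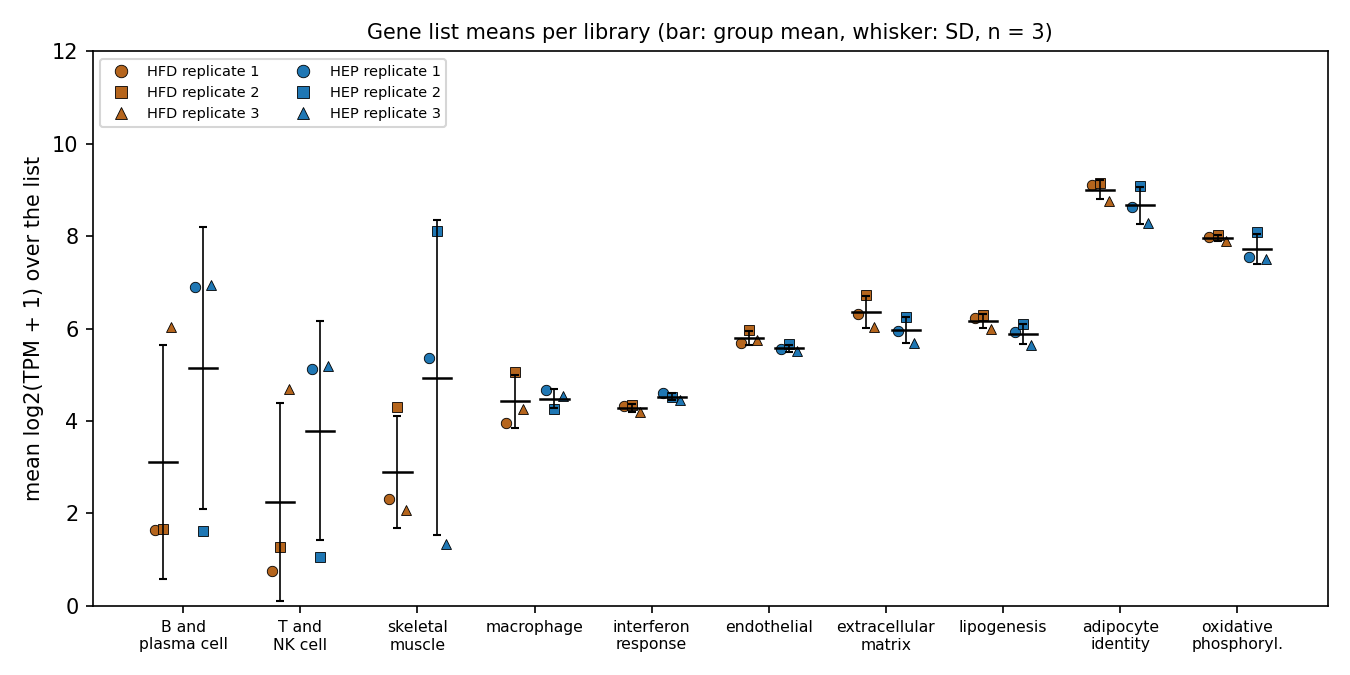
Mean log2(TPM + 1) over the members of 10 gene lists in each library, with HFD in brown and HEP in blue, the replicate number as the symbol, the group mean as a bar and the SD (n = 3) as a whisker. The B and plasma cell list ranges from 1.62 to 6.94 between libraries, while the interferon response list lies between 4.18 and 4.34 in HFD and between 4.46 and 4.60 in HEP.

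Both lymphoid lists were higher in HEP as lists. All 21 tested B and plasma cell genes had a higher HEP mean, with a median log2 fold change of 2.27 (camera adjusted p = 0.00049), and all 26 T and NK cell genes did, with a median of 1.73 (camera adjusted p = 0.00011). Neither held with the correlation between members estimated from the data (adjusted p = 0.65 with an estimated correlation for both). The mean of each list did not separate the groups, with a two-sided exact permutation p of 0.40 for B and plasma cells and 0.30 for T and NK cells, where 3 samples against 3 cannot give a p under 0.1. Leaving out 1 library moved the median of the B and plasma cell list between 1.22 without HEP replicate 3 and 4.15 without HEP replicate 2, and that of the T and NK cell list between 0.89 without HFD replicate 1 and 3.44 without HEP replicate 2. The B and plasma cell call ended without HFD replicate 2 or HEP replicate 3 and the T and NK cell call without HEP replicate 3, where the adjusted p rose as far as 0.153 and 0.111. Both calls ended with adipocyte scaling (adjusted p of 0.176 and 0.154 at medians of 2.55 and 2.03) and within the low libraries (0.717 and 0.488 at medians of -0.07 and 0.03). Both passed within the rich libraries (1.57e-10 and 5.2e-06 at medians of 1.01 and 0.47). With the lymphoid covariate, which is built from these lists, the medians were 0.09 and -0.03 and neither list passed. With lymphoid and muscle covariates the B and plasma cell list was called higher (0.000854, median 0.18) and the T and NK cell list was not called (0.38, median -0.21). The cell cycle list, with all 27 members higher in HEP by a median of 0.25, had a camera adjusted p of 0.0226 (adjusted p = 0.76 with an estimated correlation). That call ended without HFD replicate 1, HFD replicate 2 or HEP replicate 3, where the medians were 0.14, 0.15 and 0.04. Camera's direction turned in the last of these. Its median was 0.15 without HEP replicate 1, 0.47 without HFD replicate 3 and 0.58 without HEP replicate 2, with the call kept. The call also ended with quantile normalization (adjusted p = 0.101, median 0.09), with the lymphoid covariate (0.236, median -0.08) and with adipocyte scaling (0.368, median 0.55). It passed neither within the low (0.332, median -0.19) nor within the rich libraries (0.347, median 0.16), and it stood with lymphoid and muscle covariates (0.0326, median 0.06). The list's means were 2.33, 2.41 and 2.98 in HFD and 3.08, 2.20 and 3.22 in HEP, highest in the 3 libraries rich in lymphocyte genes.

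Skeletal muscle genes were also higher in HEP as a list, with 21 of 23 members higher and a median log2 fold change of 2.30 (camera adjusted p = 7.39e-05, and adjusted p = 0.65 with an estimated correlation). Most of this came from 1 library. Eno3, the muscle enolase, had 12.9, 23.3 and 16.9 TPM in HFD and 79.2, 421 and 20.1 TPM in HEP, and Mybpc2, a myosin-binding protein of fast fibres, had 0.28, 7.11 and 0.54 TPM in HFD and 28.2, 199 and 0.66 TPM in HEP. Without HEP replicate 2 the median was 0.53, still higher in HEP, while camera ranked the list below all other genes with an adjusted p of 0.693. With sample quality weights the median was -0.68 and the adjusted p 0.154. The call also ended without both libraries highest in liver transcripts (0.471, median 0.21) and within the rich libraries (0.578, median 1.54). It stood at a median of 4.05 without HEP replicate 3 and 3.45 with the lymphoid covariate. With lymphoid and muscle covariates, the latter built from this list, the median was 0.27 and the adjusted p 0.0494. Summed over the list, the TPM was 330, 1050 and 169 in HFD and 2394, 20570 and 104 in HEP. HEP replicate 2 was also high in liver transcripts, with 1024 TPM of Alb, the gene for serum albumin, and the values do not tell expression in the fat from tissue or RNA carried over at dissection or library preparation.

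Lipid synthesis genes were called lower in HEP as a list, but the list mean did not separate the groups (two-sided exact permutation p = 0.20). Library means were 6.22, 6.28 and 5.98 in HFD and 5.92, 6.09 and 5.65 in HEP. Of 26 tested members of the lipogenesis list 23 had a lower HEP mean, the median log2 fold change was -0.30 and the camera adjusted p was 2.35e-07 (adjusted p = 0.60 with an estimated correlation). Fasn, the fatty acid synthase, had 164 ± 20.04 TPM in HFD and 112 ± 16.9 TPM in HEP (mean ± SD, n = 3), and the groups did not overlap. Its log2 fold change was -0.55 ± 0.17 (SE), with an unadjusted limma p of 0.0155 and an adjusted p of 0.879. Pnpla3, a lipid droplet protein induced with lipogenesis, had 111 ± 27.2 TPM in HFD and 73.2 ± 9.04 TPM in HEP, and Slc25a1, the mitochondrial citrate carrier, had 210 ± 9.28 and 160 ± 23.9 TPM. Slc25a10, the dicarboxylate carrier of the mitochondrial membrane, is not on the list and was named for its small p. It had 98.7 ± 10.5 TPM in HFD and 61.1 ± 10.8 TPM in HEP. No list member passed, either over all genes or adjusted over the list alone, where the smallest adjusted p was 0.222 in limma. Without HFD replicate 2 the median was -0.20 with the call kept. The camera adjusted p was 0.349 at a median of -0.15 within the libraries low in lymphocyte genes and 0.000123 at a median of -0.17 within the rich. It was 0.00156 at -0.19 with the lymphoid covariate and 0.00347 at -0.32 with lymphoid and muscle covariates.

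Other adipocyte lists were called lower too, in part along with the lymphoid content. Their library means overlapped between the groups. The two-sided exact permutation p was 0.20 for adipocyte identity, 0.30 for lipolysis and lipid droplets and 0.40 for adipokines. The adipocyte identity list had 23 of 24 members lower with a median of -0.36 (camera adjusted p = 3.54e-08), the lipolysis and lipid droplet list 23 of 25 with a median of -0.30 (adjusted p = 3.93e-06 in camera), and the adipokine list 16 of 19 with a median of -0.31 (camera adjusted p = 0.000323). For all 3 lists the adjusted p was 0.60 with an estimated correlation. With the lymphoid covariate the lipolysis call ended at an adjusted p of 0.0568 with a median of -0.15, and the adipokine call at 0.328 with a median of -0.04, while adipocyte identity had 0.00712 with a median of -0.14. With lymphoid and muscle covariates all 3 were called lower, with adjusted p-values of 4.24e-06 for identity, 0.0016 for lipolysis and 0.0282 for adipokines and medians of -0.41, -0.30 and -0.34. Within the libraries low in lymphocyte genes none of the 3 lists passed, with medians of -0.04, -0.07 and 0.04. Within the rich libraries all 3 passed, with adjusted p-values of 9.59e-07, 0.000119 and 5.74e-05 and medians of -0.35, -0.27 and -0.31. Leaving out 1 library kept the 3 calls and moved the identity median to -0.23 without HFD replicate 2, -0.61 without HEP replicate 2 and -0.18 without HEP replicate 3. The adipokine median moved to -0.17, -0.55 and -0.10 without the same libraries, and the lipolysis median to -0.19 without HFD replicate 2 and -0.16 without HEP replicate 3. Lpl, the lipase that frees fatty acids from circulating triglyceride, had 4365 ± 326 TPM in HFD and 2920 ± 419 TPM in HEP, without overlap. Mgll, the monoacylglycerol lipase, had 501 ± 43.8 and 342 ± 64.8 TPM, also without overlap. Lep, the gene for the satiety hormone leptin, had 1278 ± 346 TPM in HFD and 820 ± 171 TPM in HEP, a log2 fold change of -0.63 ± 0.26 (SE), and the groups overlapped. Adipoq, which encodes adiponectin, had 3525 ± 662 and 2824 ± 963 TPM, Pparg, the master regulator of fat cells, 158 ± 25.4 and 110 ± 33.2 TPM, and Retn, which encodes resistin, 1581 ± 340 and 1089 ± 312 TPM. Slc2a4, the insulin-responsive glucose transporter, had 65.3 ± 5.90 TPM in HFD and 60.3 ± 27.0 TPM in HEP. Adjusted limma p-values were 0.879 for Lpl, Mgll, Lep, Adipoq, Pparg and Retn and 0.885 for Slc2a4.

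**Figure D2:**
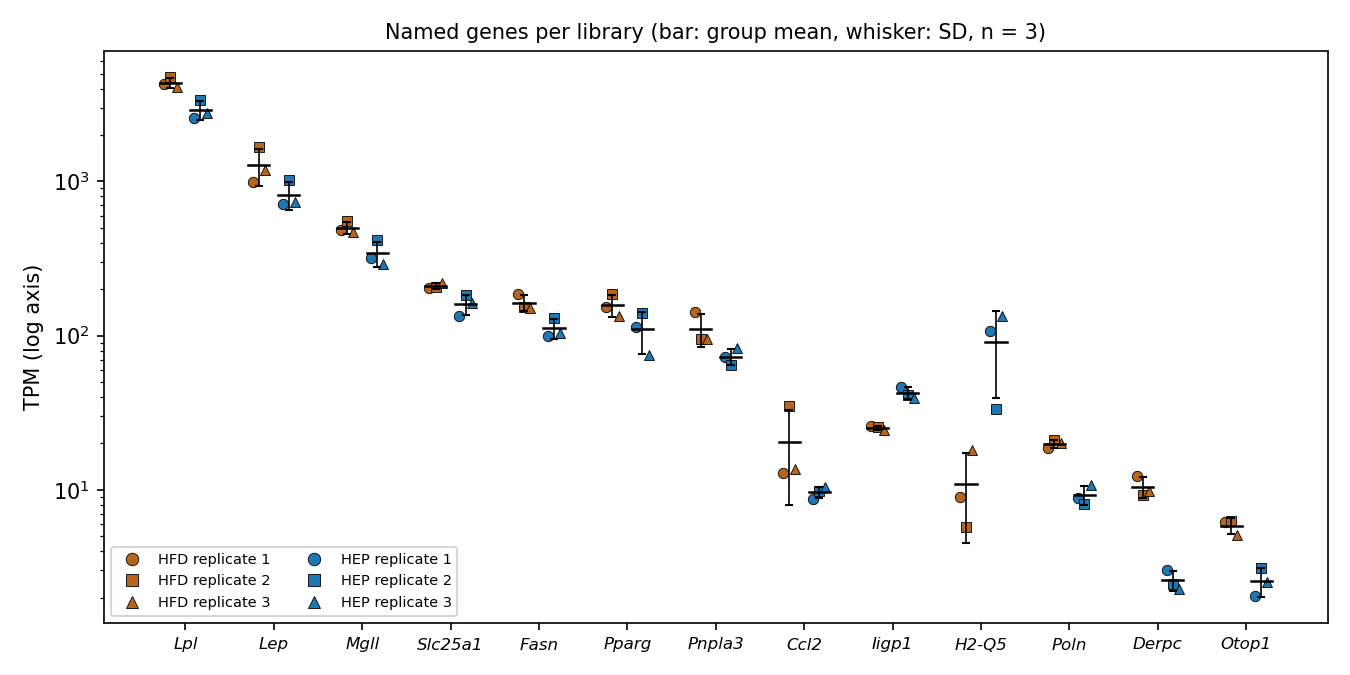
TPM on a log axis of 13 named genes in each library, with HFD in brown and HEP in blue, the replicate number as the symbol, the group mean as a bar and the SD (n = 3) as a whisker. Groups do not overlap for Fasn, Lpl and Mgll, while the Lep values of both groups overlap, with 991, 1662 and 1182 TPM in HFD and 710, 1016 and 733 TPM in HEP.

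Mitochondrial genes were called lower in HEP as lists, with a clear exception among the libraries. Of 52 nuclear genes of oxidative phosphorylation 51 had a lower HEP mean, by a median log2 fold change of -0.25 (camera adjusted p = 4.95e-12, and adjusted p = 0.60 with an estimated correlation). Ndufb3 and Ndufb8, subunits of complex I, had 344 ± 30.9 and 382 ± 30.3 TPM in HFD and 258 ± 57.9 and 286 ± 79.4 TPM in HEP. HEP replicate 2 lay with the HFD libraries: list means were 7.98, 8.02 and 7.89 in HFD and 7.55, 8.09 and 7.51 in HEP, and the two-sided exact permutation p was 0.40. Within the 3 libraries low in lymphocyte genes the list was higher in HEP, with a median of 0.08 and a camera adjusted p of 0.00126, but 0 lists passed there with an estimated correlation. The HEP arm of that fit is replicate 2 alone, the library with 20570 TPM of skeletal muscle transcripts. The list was lower within the rich libraries, with a median of -0.35 and an adjusted p of 1.15e-18. It was also lower with the lymphoid covariate, at a median of -0.11 and an adjusted p of 0.000772, and with lymphoid and muscle covariates, at -0.24 and 0.000567. Leaving out 1 library kept the call and moved the median to -0.16 without HEP replicate 1, -0.44 without HEP replicate 2 and -0.15 without HEP replicate 3. The citric acid cycle list had 20 of 20 members lower, with a median of -0.23 (camera adjusted p = 1.89e-06, and adjusted p = 0.60 with an estimated correlation), among them Idh3a, a subunit of isocitrate dehydrogenase, at 174 ± 4.87 TPM in HFD and 126 ± 25.8 TPM in HEP without overlap. Fatty acid oxidation had 20 of 26 members lower with a median of -0.26 (camera adjusted p = 1.4e-05, and adjusted p = 0.60 with an estimated correlation), and branched-chain amino acid breakdown 19 of 20 with a median of -0.27 (camera adjusted p = 4.09e-06, and adjusted p = 0.60 with an estimated correlation). The 13 genes encoded by the mitochondrial genome were all lower, with a median of -0.24 (camera adjusted p = 0.000323, and adjusted p = 0.60 with an estimated correlation), a call that ended without HFD replicate 1 or HEP replicate 1, where the adjusted p rose as far as 0.486 and the medians were -0.03 and -0.16. It also ended without both libraries highest in liver transcripts (0.0673, median -0.12) and with quantile normalization, at a median of -0.02 and an adjusted p of 0.809, and turned with lymphoid and muscle covariates, at a median of 0.10 and an adjusted p of 0.0282. Antioxidant genes had 19 of 26 members lower with a median of -0.24 (adjusted p = 9.79e-05 in camera, and adjusted p = 0.60 with an estimated correlation). With the lymphoid covariate the calls of fatty acid oxidation and antioxidant genes ended, at adjusted p-values of 0.328 and 0.295 and medians of -0.09 and -0.04. With lymphoid and muscle covariates fatty acid oxidation had 0.118 with a median of -0.19, and antioxidant genes were called lower at 0.0015 with a median of -0.27. The citric acid cycle and branched-chain amino acid calls stood with the lymphoid covariate at a median of -0.13 for both. The citric acid cycle call ended with adipocyte scaling (0.0772, median 0.11). Within the libraries low in lymphocyte genes none of these 5 lists passed, with medians between -0.12 and 0.02. Within the rich libraries all 5 passed, with medians between -0.32 and -0.19. Without HEP replicate 2 the median was -0.35 for the citric acid cycle, -0.41 for branched-chain amino acids, -0.43 for fatty acid oxidation and -0.47 for antioxidant genes. Without HEP replicate 3 it was -0.11, -0.13, -0.15 and -0.10 in the same order. Antioxidant genes had -0.13 without HFD replicate 2, and these calls were all kept.

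Thermogenic genes were called lower in HEP as a list, but the call depended on the libraries and settings used. Ucp1, the uncoupling protein of brown and beige fat, had 0.51, 1.73 and 0.19 TPM in HFD and 0.05, 0.17 and 0.21 TPM in HEP, under the minimum for testing. The thermogenic list had 15 of 20 tested members lower in HEP with a median log2 fold change of -0.11 (camera adjusted p = 0.00618, and adjusted p = 0.60 with an estimated correlation). This call ended without HFD replicate 1, HEP replicate 1 or HEP replicate 3, with an adjusted p as high as 0.304 and medians of -0.03, -0.15 and 0.09. It stood at larger medians of -0.18 without HFD replicate 2, -0.26 without HFD replicate 3 and -0.33 without HEP replicate 2. The call was also kept at larger medians with pseudocounts of 0.1 (-0.24) and 0.01 (-0.27), a mean of at least 5 TPM (-0.24), quantile normalization (-0.30), sample quality weights (-0.43) and without both libraries highest in liver transcripts (-0.33). The call ended with the lymphoid covariate (0.769, median 0.13), with lymphoid and muscle covariates (0.747, median -0.20) and with nuclear protein-coding genes only (0.0545, median -0.18). The adjusted p was 0.156 at a median of 0.01 within the libraries low in lymphocyte genes and 0.000119 at -0.23 within the rich. Otop1, a proton channel enriched in brown fat, had 5.85 ± 0.68 TPM in HFD and 2.56 ± 0.54 TPM in HEP without overlap, and its limma p adjusted over the list alone was 0.0993, the smallest of any list. Cidea, a lipid droplet protein of brown and beige fat cells, had 16.4 ± 4.03 and 10.9 ± 1.90 TPM. The list of heat production independent of Ucp1 had 8 members higher and 7 lower, with a camera adjusted p of 0.447.

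Matrix and vessel genes were called lower in HEP as lists. Library means of the matrix list overlapped, with 6.25 in HEP replicate 2 and 6.04 in HFD replicate 3 (two-sided exact permutation p = 0.20). Those of the endothelial list did not overlap (0.10 in the same test, the smallest possible). Of 31 extracellular matrix genes 30 had a lower HEP mean, with a median log2 fold change of -0.41 (camera adjusted p = 1.29e-10, and adjusted p = 0.60 with an estimated correlation). At the preset correlation the call stood in each leave-one-out fit, with an adjusted p of 2.31e-06 at most, but 0 lists passed in any of these fits with an estimated correlation. The median moved to -0.27 without HFD replicate 2 and to -0.63 without HFD replicate 3, and it was -0.21 with the lymphoid covariate and -0.19 within the libraries rich in lymphocyte genes. Fbn1, the microfibril protein fibrillin-1, had 17.3 ± 4.81 TPM in HFD and 10.9 ± 1.45 TPM in HEP, Col4a2, a basement membrane collagen chain, 237 ± 59.7 and 167 ± 24.7 TPM, Timp1, an inhibitor of matrix proteases, 5.10 ± 2.58 and 2.18 ± 0.45 TPM, and Col1a1, a chain of fibrillar collagen, 161 ± 62.3 and 101 ± 38.2 TPM. Of 19 endothelial genes 17 were lower, with a median of -0.26 (camera adjusted p = 3.93e-06, and adjusted p = 0.60 with an estimated correlation), including Esam, an adhesion molecule of endothelial junctions, at 101 ± 12.5 and 76.6 ± 10.3 TPM, and Nos3, the endothelial nitric oxide synthase, at 13.3 ± 0.98 and 10.2 ± 0.56 TPM. Fat cell progenitor genes had 14 of 19 members lower with a median of -0.28 (camera adjusted p = 0.00435, and adjusted p = 0.60 with an estimated correlation), and smooth muscle and pericyte genes 12 of 15 with a median of -0.18 (camera adjusted p = 0.00874, and adjusted p = 0.60 with an estimated correlation), a call that ended without HFD replicate 2 at an adjusted p of 0.215 and a median of -0.06. Cholesterol synthesis genes had 15 of 21 members lower with a median of -0.16 (camera adjusted p = 0.000227, and adjusted p = 0.60 with an estimated correlation). Nsdhl, Mvk and Fdps, enzymes of that pathway, had 20.5 ± 0.81, 18.7 ± 3.30 and 40.3 ± 5.16 TPM in HFD and 15.1 ± 1.84, 12.3 ± 2.13 and 30.1 ± 3.13 TPM in HEP, each without overlap. The progenitor call ended with quantile normalization at a larger median (adjusted p = 0.11, median -0.43), with the lymphoid covariate (0.328, median -0.17) and with lymphoid and muscle covariates (0.138, median -0.30), all in camera. It also ended within the rich libraries (0.0877, median -0.09). The smooth muscle call ended with the lymphoid covariate (0.191, median -0.14), with lymphoid and muscle covariates (0.0562, median -0.24) and with adipocyte scaling (0.0692, median 0.16). It ended too within the rich libraries (0.0766, median -0.06). Within the libraries low in lymphocyte genes none of these 4 lists passed, with medians of -0.21 for endothelial and cholesterol synthesis genes, -0.08 for progenitor genes and -0.24 for smooth muscle genes. Endothelial and cholesterol synthesis genes were called lower within the rich, at medians of -0.20 and -0.18. Without HFD replicate 2 the median was -0.14 for endothelial and -0.08 for cholesterol synthesis genes. Cholesterol synthesis genes had -0.24 without HFD replicate 3 and -0.32 with quantile normalization, and progenitor genes had -0.10 without HEP replicate 3. Each of these calls was kept.

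Macrophage genes did not differ as a list. Of 27 members 14 had a higher and 13 a lower HEP mean, and the camera adjusted p was 0.24. Adgre1, which encodes the macrophage marker F4/80, had 12.7, 35.2 and 8.26 TPM in HFD and 17.0, 14.8 and 14.6 TPM in HEP, a log2 fold change of -0.02 ± 0.49 (SE). HFD replicate 2 decided the direction: without it the list was higher in HEP with a median of 0.29 and an adjusted p of 0.000119, and without HFD replicate 1 it was lower with a median of -0.23 and an adjusted p of 0.00217, both in camera. Neither passed with an estimated correlation, where 0 lists were called in both fits. Folr2 and Mrc1, markers of resident macrophages, had 46.6 ± 9.10 and 36.8 ± 7.16 TPM in HFD and 34.1 ± 3.34 and 27.8 ± 5.83 TPM in HEP. The inflammation list had 16 of 23 members higher and a camera adjusted p of 0.63. Ccl2, the monocyte chemoattractant, had 12.9, 35.0 and 13.6 TPM in HFD and 8.72, 9.81 and 10.4 TPM in HEP, without overlap, and Lcn2, the iron-binding protein lipocalin-2, 3.69 ± 2.33 and 1.06 ± 0.40 TPM, with adjusted limma p-values of 0.879. Tnf had 0.50, 1.08 and 3.09 TPM in HFD and 6.03, 0.44 and 4.81 TPM in HEP, high in the libraries with many lymphocyte transcripts.

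Interferon response genes were higher in HEP as a list. Of 24 members 22 had a higher HEP mean, with a median log2 fold change of 0.22 (camera adjusted p = 0.00191, and adjusted p = 0.60 with an estimated correlation). Usp18, a negative regulator of interferon signalling, had 9.50 ± 0.61 TPM in HFD and 13.5 ± 2.28 TPM in HEP, Ifit2, an interferon-induced RNA-binding protein, 12.3 ± 1.63 and 16.0 ± 1.44 TPM, and Ifi44 3.28 ± 0.84 and 4.77 ± 0.23 TPM, each without overlap. Iigp1, an interferon-induced GTPase that is not on the list, had 25.3 ± 0.79 TPM in HFD and 42.5 ± 3.69 TPM in HEP. Its unadjusted p was the smallest of the named higher genes (limma p of 0.00143, adjusted p = 0.879). The list's call ended without HFD replicate 3 or HEP replicate 2, with an adjusted p as high as 0.286 and medians of 0.11 and 0.13. It also ended with sample quality weights (0.109, median 0.16) and without both libraries highest in liver transcripts, at a larger median of 0.25 (0.0952). It stood with the lymphoid covariate (5.65e-08, median 0.24), with lymphoid and muscle covariates (2.69e-06, median 0.25) and with quantile normalization (0.00432, median 0.11). The median was 0.14 within the low and 0.34 within the rich libraries, where an arm is 1 library. Library means did not overlap between the groups for 3 of the 34 lists, endothelial, cholesterol synthesis and interferon response, where chance gives 3.4.

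**Figure D3:**
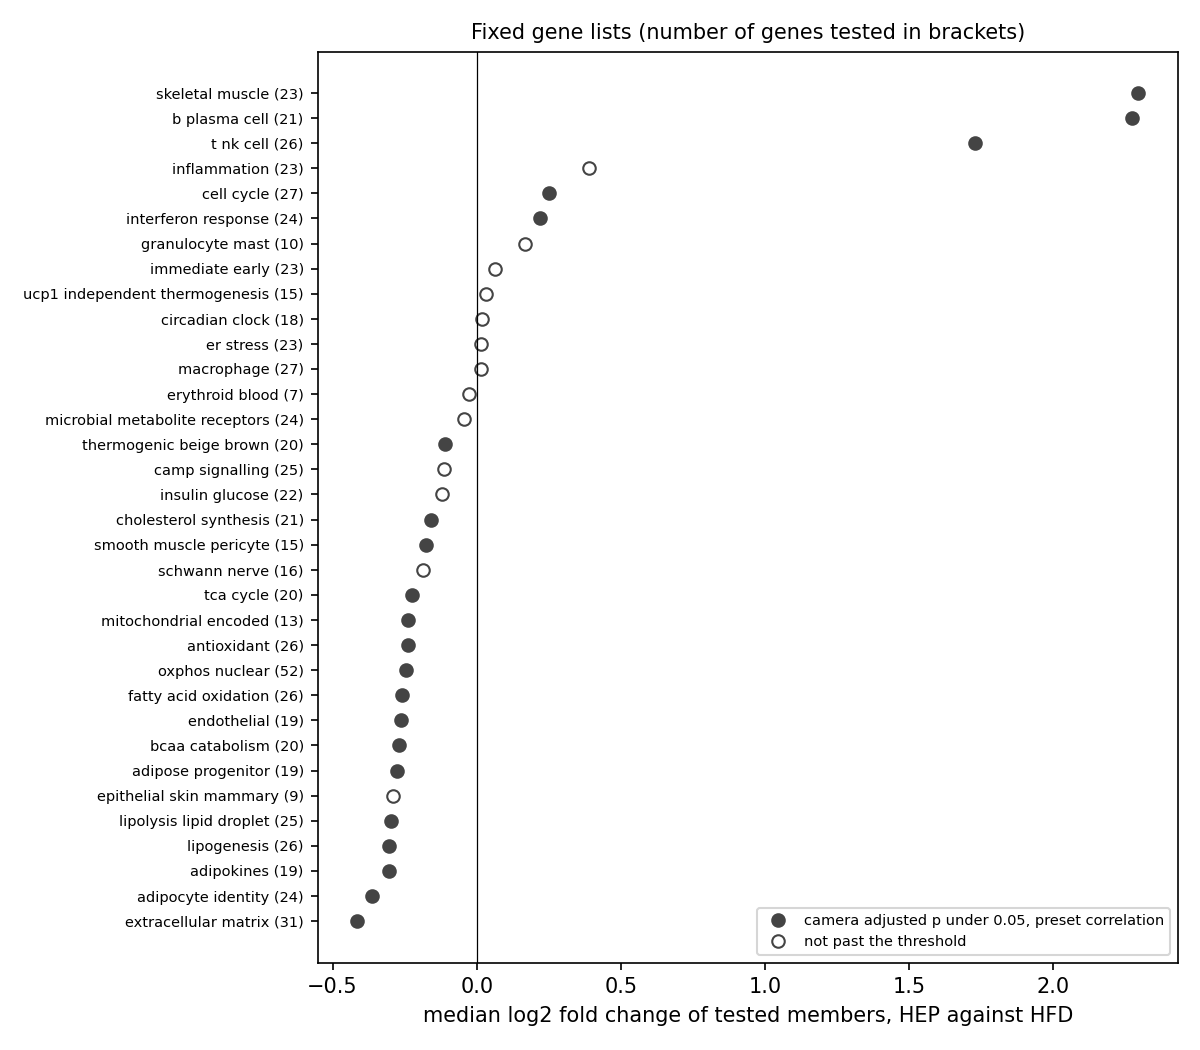
Median log2 fold change, HEP against HFD, of the tested members of each of the 34 fixed gene lists, with filled points for a camera adjusted p under 0.05 at the preset correlation and open points for the rest. Of the 21 filled points 16 are lists called lower and 5 are lists called higher, and with an estimated correlation 0 of the 34 lists passed.

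Across the 34 lists, camera with a preset correlation of 0.01 called 5 higher and 16 lower. With an estimated correlation 0 passed, and fry, which asks whether a list's members move on balance 1 way, passed 0 with a smallest adjusted p of 0.682, or 0.612 for movement in either direction. Over the 23 other fits, 0 lists passed in any with an estimated correlation. That test also called 0 lists when the libraries were split by lymphocyte genes, where 3333 genes passed in limma. A count of 0 with an estimated correlation therefore cannot tell an absent list effect from a present one. At the preset correlation 7 of the 21 called lists kept their call and camera's direction in all 21 fits with at least 2 libraries per arm: extracellular matrix, lipogenesis, oxidative phosphorylation, branched-chain amino acid breakdown, adipocyte identity, endothelial and cholesterol synthesis. Each is a list called lower. These fits reuse the same libraries and the preset correlation, and they include the adipocyte scaling described below. Keeping a call in all of them is therefore no independent support. Within the libraries low in lymphocyte genes camera's direction against all other genes turned for 10 of the 21, and for 7 of these the sign of the median turned as well. Of the 21, the call and direction were kept by 11 with the lymphoid covariate and by 15 with lymphoid and muscle covariates. In the fits with an arm of 1 library, 17 had the same call and direction within the rich libraries and 3 within the low. Sample quality weights moved the median of 15 of the 21 by over 1.5 times, and leaving out both libraries highest in liver transcripts that of 13. Adipocyte scaling, which raised the median of all genes by 0.30, left 14 of the 16 lower lists with a median above 0, while camera's direction against all other genes turned for 0 of them. Such scaling divides all genes of a library by 1 factor, so a direction against all other genes could hardly turn. The lists not called were epithelial, skin and mammary genes (camera adjusted p = 0.0525), cyclic AMP signalling (0.0989), Schwann cell and nerve (0.114), receptors of microbial metabolites (0.162), insulin and glucose handling (0.405), granulocytes and mast cells (0.447), the circadian clock (0.447), endoplasmic reticulum stress (0.749), blood cells (0.792) and immediate early genes (0.897), besides the 3 given above. Leaving out 1 library brought 5 of them past the threshold: epithelial genes without HFD replicate 3 or HEP replicate 3 (adjusted p as low as 0.004), Schwann cell genes without HFD replicate 3 or HEP replicate 2 (0.0107), granulocyte genes without HFD replicate 3 (0.0159), microbial metabolite receptors without HEP replicate 2 (0.0235) and cyclic AMP signalling without HFD replicate 3 (0.0426), all in camera at the preset correlation, and 0 lists passed in these fits with an estimated correlation. In some of the 23 fits 9 of the 13 passed. In 5 of the 13 lists not called, macrophage, clock, Ucp1-independent heat production, endoplasmic reticulum stress and immediate early genes, the median was above 0 while camera, which sets a list against all other genes, gave a lower direction. The median of all genes was 0.07, and the reason for the opposite directions was not tested.

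The genes with the smallest p-values in each direction did not pass the test and are named as such. Derpc (ENSMUSG00000117748) had 12.3, 9.29 and 9.90 TPM in HFD and 3.02, 2.46 and 2.29 TPM in HEP, a log2 fold change of -1.68 ± 0.21 (SE) with a limma adjusted p of 0.78. It overlaps Chtf8 on the same strand, so the split of reads between both genes is uncertain. Poln (ENSMUSG00000045102), a DNA polymerase gene, had 19.9 ± 1.13 TPM in HFD and 9.25 ± 1.33 TPM in HEP and overlaps Haus3 on the same strand. The ribosomal protein pseudogene Rpl38-ps2 (ENSMUSG00000080921) was listed at 65.8, 16.9 and 163 TPM in HFD and at 0 in the 3 HEP libraries, and its reads cannot be separated with certainty from those of Rpl38, which had 1418 ± 392 and 1679 ± 540 TPM. H2-Q5 (ENSMUSG00000055413), a class I histocompatibility gene annotated as a loss-of-function allele, had 8.93, 5.78 and 18.2 TPM in HFD and 107, 33.3 and 134 TPM in HEP, a log2 fold change of 2.87 ± 0.61 (SE) with a limma adjusted p of 0.879, and it has near-identical neighbours. The labels gave the genotype as wild type and no substrain, and TPM holds no sequence, so a difference of alleles between the mice of both groups was not excluded for these 4 genes.

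Among the other lower genes, Cdkn2c, an inhibitor of cyclin-dependent kinases, had 120 ± 14.6 TPM in HFD and 76.0 ± 4.70 TPM in HEP, and Gpt, an alanine aminotransferase, had 80.5 ± 8.38 and 48.0 ± 10.7 TPM. Slc25a35, a mitochondrial carrier, had 19.4 ± 0.30 and 13.0 ± 0.36 TPM, Slc18b1, a polyamine transporter, 24.4 ± 1.84 and 15.4 ± 1.89 TPM, and Btg3, an antiproliferative factor, 27.5 ± 3.76 and 17.5 ± 0.69 TPM. Among the higher genes, Tuba4a, an alpha-tubulin, had 13.9 ± 11.1 TPM in HFD and 50.9 ± 17.7 TPM in HEP, Bin1, a membrane-bending protein abundant in muscle, 32.0 ± 9.65 and 63.1 ± 4.46 TPM, and Phtf2 6.05 ± 1.03 and 11.5 ± 0.81 TPM. Capn3, the muscle calpain, and Asb2, a muscle ubiquitin ligase subunit, had 10.5 and 21.9 TPM in HEP replicate 2, the library with the most muscle transcripts, and 2.88 to 4.28 TPM in the other HEP libraries, against 0.45 to 1.30 TPM in HFD. Prr33 had 2.76 ± 1.15 and 9.98 ± 4.41 TPM, Gpcpd1, a glycerophosphocholine phosphodiesterase, 24.4 ± 3.78 and 42.3 ± 8.70 TPM, and Tomm20, a receptor of the mitochondrial import machinery, 50.7 ± 3.13 and 68.9 ± 1.31 TPM. The adjusted limma p of each was 0.879, and the groups did not overlap.

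Of 2829 terms from gene ontology, KEGG and Reactome, camera with the preset correlation called 173 higher and 195 lower in HEP, and 0 with an estimated correlation, where the smallest adjusted p was 0.999. KEGG's oxidative phosphorylation term had 106 of 121 genes lower with a median log2 fold change of -0.21 (camera adjusted p = 3.2e-09), and its term for valine, leucine and isoleucine degradation had 40 of 49 genes lower with a median of -0.28 (adjusted p = 5.81e-07 in camera). Reactome's collagen formation term had 42 of 48 genes lower with a median of -0.36 (camera adjusted p = 3.91e-08). The gene ontology term for B cell receptor signalling had 100 of 103 genes higher with a median of 1.21 (camera adjusted p = 5.27e-09).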

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

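The covariate, adipocyte scaling, protein-coding and within-library fits and the fit without both libraries highest in liver transcripts were chosen after the result was seen, and the others were planned. The counts of 0 genes higher and 0 lower in HEP (limma, adjusted p under 0.05) held in all fits except without HEP replicate 2, where 1 higher gene passed, so the count of higher genes ranged from 0 to 1 over the fits that leave out a replicate. With an unadjusted p under 0.05 and at least a 2-fold change, 40 genes were higher and 24 lower. Quantile normalization moved the median log2 fold change of all genes by -0.13 and adipocyte scaling by 0.30.

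The thermogenic list's camera adjusted p ranged from 6.99e-05 to 0.304 over the fits that leave out a replicate. It was 0.769 (median 0.13) with the lymphoid covariate, 0.747 (-0.20) with lymphoid and muscle covariates, 0.0545 (-0.18) with nuclear protein-coding genes only, and 0.156 (0.01) with the direction reversed within the lymphoid-poor libraries, against a median of -0.11 over all libraries and 0.000119 (-0.23) within the lymphoid-rich. Lipogenesis had 0.349 and oxidative phosphorylation a reversed 0.00126 within the lymphoid-poor libraries, and both were lower at 0.000123 and 1.15e-18 within the lymphoid-rich. These 3 lists had an adjusted p of 0.60 with an estimated correlation and 0.682 in fry. The macrophage list ranged from 0.000119 (reversed, without HFD replicate 2) to 0.41 over the fits that leave out a replicate, and was reversed at 0.0254 within the lymphoid-rich libraries. Reversed here means camera's direction against all other genes. The cause was not tested for the protein-coding fit, while the within-library fits hold 3 libraries with an arm of 1.

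Of 56 named genes, 52 kept their direction in each alternative fit that gave them a value, 23 fits for 47 of the 56 and 22 for 9, and 4 did not. Log2 fold changes turned to 0.038 for Adipoq within the lymphoid-poor libraries, and for Slc2a4 to 0.058 with the lymphoid covariate, 0.13 with adipocyte scaling and 0.39 within the lymphoid-poor libraries, with a range of -0.531 to 0.091 over the fits that leave out a replicate. Adgre1 ranged from -0.437 to 0.546 over those fits, above 0 without HFD replicate 2, HEP replicate 2 or HEP replicate 3, and turned to 0.19 with the lymphoid covariate, 0.07 with both covariates, 0.31 with adipocyte scaling and 0.86 within the lymphoid-rich libraries. Tnf turned to -0.04 with both covariates and -0.30 within the lymphoid-poor libraries.

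With the replicate number as a block, 0 genes passed and 576 had an unadjusted p under 0.05, and camera called 22 lists. Deviations of same-numbered libraries correlated at -0.35, 0.37 and 0.65, and not every sample correlated best with its own number, so no pairing was seen. HFD replicate 3 correlated at 0.50, -0.71 and 0.65 with HEP replicates 1 to 3, which follows their lymphocyte content. A pairing under that content was therefore not excluded. Depth limits could not be given, as TPM keeps none.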

Other observations

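The tests of dilution, shared noise, overlapping genes, lymphoid cells, H2-Q5 with a covariate and sample splits, each comparison with a partner gene that had not moved, and the fall needed in the other H2-Q genes, were chosen after the result was seen, while those of 5 lymph node genes and of the summed H2-Q genes were fixed before. Transcripts typical of liver stood out in HFD replicate 1 and HEP replicate 2, on a list of 16 liver genes written after they were seen. Alb, the gene for serum albumin, had 664, 27.5 and 48.8 TPM in HFD and 9.20, 1024 and 39.3 TPM in HEP. All 16 genes were higher in both libraries than in the others, 4 of them were at 1 TPM or more in every library, and none is on another list. Apoa2, an apolipoprotein of high-density lipoprotein, had 505, 14.0 and 29.3 TPM in HFD and 1.37, 768 and 22.0 TPM in HEP, and the list's summed TPM was 2674, 82.7 and 180 in HFD and 24.3, 4219 and 150 in HEP. Without these 2 libraries 0 genes passed in limma and camera called 19 lists. Saa1, an acute-phase serum amyloid gene chosen after its values were seen, was high in HFD replicate 1 at 148 TPM, with 4.55 and 9.98 TPM in the other HFD libraries and 0.17, 3.54 and 5.83 TPM in HEP, and so did not follow Alb in HEP replicate 2. Whether the liver transcripts of both libraries and the skeletal muscle transcripts of HEP replicate 2 were carried over at dissection or library preparation was not tested and stays open, and with it what the skeletal muscle call means. Ribosomal RNA genes took 2.32% of the TPM in HFD replicate 2 and 0.17% to 0.54% in the others, and mitochondrially encoded genes took 13.9% to 23.0%.

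A candidate explanation for the lymphocyte genes of HFD replicate 3 and HEP replicates 1 and 3 is lymph node tissue in the fat pad samples, as this depot encloses a node. Of 5 node stroma, venule and sinus genes, 4 were required to differ 4-fold (TPM + 1) in both groups, a bound fixed beforehand. The bound was met by 2. Ccl19 had 2.95, 5.35 and 198 TPM in HFD and 168, 3.87 and 163 TPM in HEP. Marco had 1.36, 2.05 and 63.2 TPM in HFD and 62.1, 1.30 and 94.9 TPM in HEP. Chst4 and Madcam1, at most 1.49 and 2.09 TPM, could not reach 4-fold on that scale. The required 4 were thus out of reach, and the shortfall decides nothing. All 5 were higher in each of the 3 libraries than in each of the others, but Chst4, Madcam1 and Siglec1 were at most 8.90 TPM, and 3 of the 5 genes reached 1 TPM in every library low in lymphocyte genes, as did 14 of the 47 B and T cell genes. Further node genes, Ccl21a with 0.87, 0.28 and 519 TPM in HFD and 695, 0 and 670 TPM in HEP, and Glycam1 of the high endothelial venule with 0, 0 and 132 and 120, 0 and 195 TPM, had been seen before the test. The lymphoid score did not follow diet in every library. It was 5.37 in HFD replicate 3, without hesperidin, and 1.33 in HEP replicate 2, with it. A rise of lymphoid cells with hesperidin on average stays open: the mean score was 1.80 higher in HEP with a two-sided exact permutation p of 0.30. As 3 against 3 cannot go below 0.1, that test could not decide it. An effect of diet beside node content cannot be told apart here.

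The lists called lower in HEP, 16 lists with 359 genes, may reflect shared noise between genes or dilution of fat RNA by lymphoid RNA. In 35 of 100 simulated data sets with the real residuals' shared noise and no effect, camera with the preset correlation called at least the 21 lists of the real data. The most was 29. Shared noise without a group effect could thus give the number of called lists. The residuals keep the differences in lymphoid content within each group. Any dilution that goes with them is part of this noise, so the simulation does not separate both explanations. The mean log2(TPM + 1) of the 359 genes differed by -0.23 (95% interval -0.69 to 0.23) between HEP and HFD. With the lymphoid covariate it differed by -0.10 (-0.37 to 0.17), an interval that holds both 0 and the uncorrected difference. Library means were 6.66, 6.74 and 6.49 in HFD and 6.34, 6.68 and 6.17 in HEP, lower in each library rich in lymphocyte genes. The slope on the lymphoid score was -0.073 ± 0.019 (SE), so these genes fell with lymphoid content. Their lists were chosen as lower in HEP in the same libraries, and TPM has a fixed total per library. The group difference and the slope could follow in part from both, and are no independent support. Whether dilution explains the difference between the groups stays open. An effect of hesperidin on these genes was not excluded by either test.

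For the genes with the smallest p-values, reads shared with another gene are a candidate explanation. The summed TPM of Derpc and Chtf8 had a log2 fold change of 0.077 (95% interval -0.36 to 0.52), which excludes the -1.68 of Derpc. That exclusion says little, since in HFD Chtf8 had 20.3 TPM and Derpc 10.5 TPM. With Chtf8 unmoved the sum could not have fallen so far. The interval narrowly excludes the -0.39 that would follow if Chtf8 had not moved, while Chtf8 alone had 0.56 (-0.07 to 1.18), which holds 0. For Poln and Haus3 the sum had -0.41 (-1.11 to 0.30), which holds both 0 and the -0.56 that would follow if Haus3 had not moved, and so decides nothing. For H2-Q5, lymphoid content as the whole cause is argued against by a log2 fold change of 2.24 (1.69 to 2.79) with the lymphoid covariate, though the limma adjusted p was 0.287, and by HEP replicate 2, low in lymphocyte genes, lying above HFD replicate 3 with 33.3 against 18.2 TPM. The sum with H2-Q4, H2-Q6, H2-Q7 and H2-Q10 had 0.59 (-0.05 to 1.23) with that covariate, which met the condition fixed beforehand of holding 0 and excluding 2.24, but 0.18 would follow if the other 4 abundant genes had not moved, so the condition decides little. The other 4 alone had 0.45 (-0.19 to 1.09), a higher and not a lower value, which narrowly excludes the -0.22 needed if all added reads of H2-Q5 had been taken from them. Among these, H2-Q10 was highest in both libraries high in liver transcripts, at 85.0 TPM in HFD replicate 1 and 70.6 TPM in HEP replicate 2. It had 24.4 to 29.6 TPM in the others, so both intervals also carry that difference between libraries. As the interval of the sum still holds 0, shared reads stay open, with weak evidence against these 4 genes as their only source. A biological difference stays open too, as does a substrain or allele difference between the mice of both groups for H2-Q5, Derpc, Poln and Rpl38-ps2, which TPM cannot show and which was not tested.

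The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. All 10 splits gave at least the 0 genes of the real split, and the highest other gave 3333 genes. That split set HFD replicates 1 and 2 and HEP replicate 2 against the rest, which points to the structure of the samples by lymphocyte genes. For the lists, 3 of the 10 splits, the real one included, gave at least its 21 called lists, and the highest other gave 25. Genes listed at 0 in 1 group and at 1 TPM or more in every library of the other numbered 6 in the real split and 1 to 8 in the other splits, apart from 160 in the split by lymphocyte genes. Among these 6 is the pseudogene Gm35781, chosen after its values were seen, listed at 0 in the 3 HFD libraries and at 3.72, 5.45 and 3.09 TPM in HEP.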
